A study of Homo sapiens with 10 samples.

How the data were processed

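Expression was measured on 10 Illumina beadchip arrays of LNCaP and C4-2B cells, 3 DMSO and 3 enzalutamide-resistant LNCaP arrays and 2 DMSO and 2 enzalutamide-resistant C4-2B arrays, grouped by their titles. The non-normalized table deposited by the authors holds 1 probe intensity per array on a linear scale, exported from GenomeStudio per the submitters' processing notes, with the version not given in the sources used here. It also holds a detection p-value per probe and array, which per the file headers compares the probe with the array's negative controls (770 as implied by the smallest step of the p-values). A second table deposited by the authors holds processed intensity values, whose scale and normalization are not stated. From the values, these are linear and background-subtracted, with 26.9% to 27.6% of values below 0 and array medians of 3.5 to 4.1. Sorted values lie within 1 intensity unit of each other, at 0.99 of ranks, in each of 3 sets: the first C4-2B pair, the second C4-2B pair and the 6 LNCaP arrays. It served only as an alternative. All value columns were mapped to samples.

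The probe annotation named 1 gene symbol for 30106 of 47307 probes, several for 8 and none for 17193, with 20042 distinct symbols. The identifiers of 30067 probes were found in the GRCh38.p14 gene table, which was used for names and the order of neighbouring genes only, and 0 symbols needed an update. The annotation can be old, and probes can also capture near-identical transcripts. Genes it does not name are not analysed here, and probes without a symbol were only counted.

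The non-normalized intensities were background-corrected by normexp from the detection p-values, with an offset of 16, quantile-normalized and taken to log2 (the neqc steps of limma). Each gene was represented by its probe with the highest mean, and genes were kept where the detection p was under 0.01 on all arrays of at least 1 group, which left 10716 genes. A probe with a detection p of 0.01 or more was called not above background. All 10 arrays were fitted with 1 mean per group by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were resistant minus DMSO in each line, the difference of these changes between lines, and C4-2B DMSO minus LNCaP DMSO. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

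Before the data were examined, 26 gene lists (21 pathway lists and 5 lists of cell type markers, 423 members, of which 392 were named on the array) were fixed together with the design, the alternatives and the rule for named genes. That rule always named ACKR3, KLK3 and NR3C1. It added the 10 highest and 10 lowest changes that passed in each line and up to 4 members with the largest changes per list. It also added the 5 highest and 5 lowest for the difference between lines and between the DMSO lines, and the 5 largest shared changes per direction. A further 27 list members that complete a small count, the endothelial, fibroblast, leukocyte and basal markers that did not pass, and the examples given for the difference between lines were named after their values were seen. The 22 lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, adjusted over lists, and also with an estimated correlation and by fry. Genes called in 1 line were tested as sets in the other by fry, adjusted over 4 sets. The steroid receptor, basal, fibroblast and leukocyte lists had 2 tested members each, so only member values are given.

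Steps were tested on simulated data of 10716 genes with 200 genes changed. For LNCaP, a log2 change of 1 was recovered in 98.9% to 100% of genes and 0.3% to 0.6% of calls were false. For C4-2B, 97.6% were recovered. Of the C4-2B calls 9.9% were false when the arrays of a pair shared deviations and 56.4% when they varied independently. The false share depends on the number of genes changed, so it does not carry over to the real calls. The simulated C4-2B arrays carried the larger spread of the real ones. Replicate numbers did not pair the LNCaP arrays.

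Alternatives fixed beforehand changed the background correction or its offset, the normalization, the values used, the detection filter, the probe per gene, the arrays in the fit, the variance model, array weights, the replicate block, the replicates, the list test and the thresholds. The C4-2B set as a block, array weights by line and both together were added after seeing the data. The dose was in no model, since the sample labels and the series design give it differently.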

Results

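Gene expression was measured on 10 Illumina beadchip arrays in 2 human prostate cancer cell lines that had been selected for growth under enzalutamide, an androgen receptor antagonist also called MDV3100, or kept in 0.1% DMSO as the control. LNCaP is an androgen-responsive line from a lymph node metastasis, and C4-2B is a castration-resistant line derived from it. LNCaP was covered by 3 DMSO and 3 enzalutamide-resistant arrays, and C4-2B by 2 DMSO and 2 enzalutamide-resistant arrays, after at least 3 months of selection. The sample labels give the enzalutamide concentration as 1 µM for LNCaP and 10 µM for C4-2B, whereas the series design gives 10 µM and 1 µM, so dose entered no comparison. Between 15601 and 17339 of the 47307 probes were above background on each array, and 10716 genes were tested. The median standard deviation between arrays of a group was 0.0889 (log2, n = 3) in LNCaP DMSO, 0.0874 (n = 3) in LNCaP resistant, 0.151 (n = 2) in C4-2B DMSO and 0.148 (n = 2) in C4-2B resistant arrays, and the number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

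All changes below are log2 differences, resistant minus DMSO, ± SE, with limma's Benjamini-Hochberg adjusted p. The C4-2B arrays came in 2 sets, each of 1 DMSO and 1 resistant array normalized together, as inferred from sorted values of the authors' processed table and stated nowhere in the labels. C4-2B lists that passed are therefore given with the change within each such pair and with the set as a block, which leaves the log2 change as it is. All 2106 C4-2B gene calls also passed with the set as a block, so for single genes the block lent no further support. Pair values are also given for the genes with the largest C4-2B changes above background. They are given too for members whose change differed more than 3-fold between the pairs, unless the change is given as a bound. Where every array of a group was below background, the change is given as a bound, at least so many fold: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal above background and the probe's own signal.

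The series title concerns the chemokine receptor CXCR7 and MAPK signalling in enzalutamide resistance. ACKR3, the gene of CXCR7, a receptor that scavenges CXCL12 and signals through arrestin, rose in the resistant cells of both lines. In LNCaP it rose by 2.84 ± 0.33 (7.16-fold, n = 3 and 3, adjusted p = 8.98e-05), from a mean log2 level of 7.12 to 9.96. In C4-2B it rose by 1.58 ± 0.40 (2.98-fold, n = 2 and 2, adjusted p = 0.0196), from 8.39 to 9.97, with 0.98 and 2.18 within the pairs and an adjusted p of 0.000229 with the set as a block. The C4-2B change was smaller than the LNCaP change by 1.26 ± 0.52, a difference that did not pass (adjusted p = 0.105). The C4-2B call rested on single arrays. It was lost without resistant replicate 1 (1.32, adjusted p = 0.111), and the change was 0.71 without DMSO replicate 2 and 2.44 without DMSO replicate 1. It was also lost with the C4-2B arrays fitted alone (adjusted p = 0.211) or without the detection filter (adjusted p = 0.0503).

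KLK3, which encodes prostate-specific antigen and is induced by the androgen receptor, fell by 2.10 ± 0.13 in resistant LNCaP (4.30-fold, adjusted p = 9.08e-07) and was above background on 1 of the 3 resistant arrays. In C4-2B it was above background on 1 of the 2 DMSO arrays and on 0 of the 2 resistant arrays, a difference of at least 1.01-fold that did not pass (adjusted p = 0.17, adjusted p = 0.119 with the set as a block). With KLK3 mostly at background in C4-2B, its change cannot be compared between the lines. NR3C1, the glucocorticoid receptor gene, was represented by 3 probes, and none was above background on any of the 10 arrays.

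**Figure D1:**
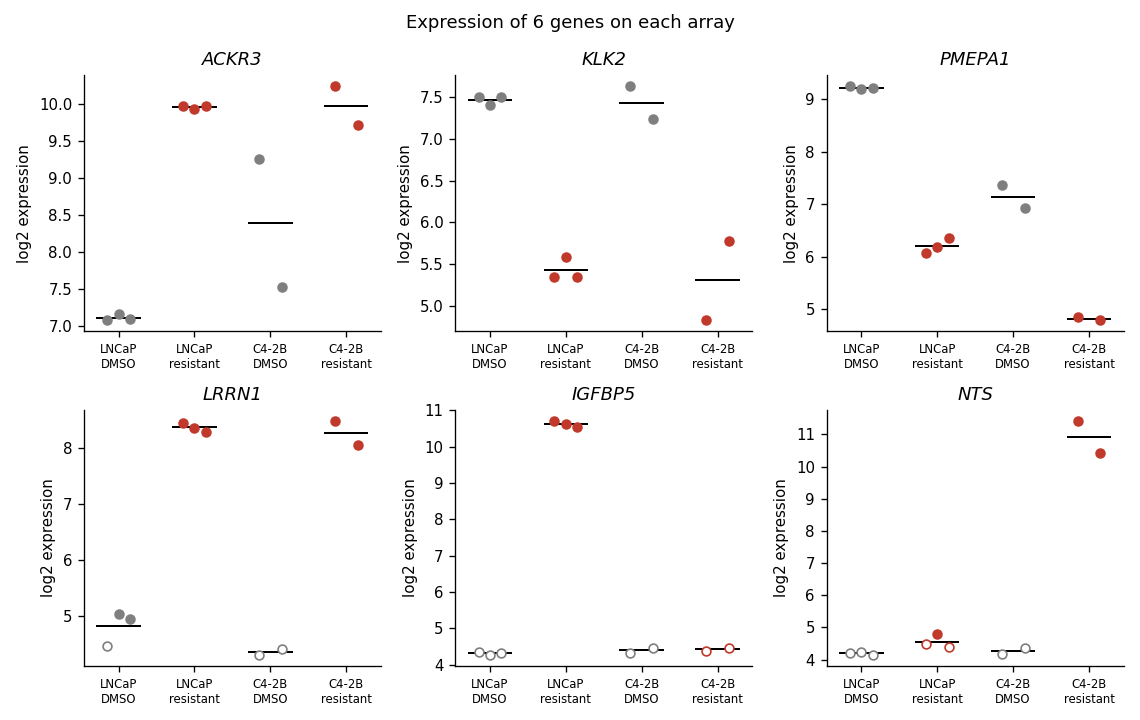
Log2 expression (vertical axis) of ACKR3, KLK2, PMEPA1, LRRN1, IGFBP5 and NTS on each of the 10 arrays (points) in the 4 groups (horizontal axis), with the group mean as a bar; open points mark arrays where the probe was not above background. ACKR3 rose by 2.84 in LNCaP and by 1.58 in C4-2B, KLK2 fell by 2.05 and by 2.12, and IGFBP5 was above background only on the 3 resistant LNCaP arrays.

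Among the largest changes in resistant LNCaP were rises of IGFBP5, CAMK2N1 and COLEC12 and falls of SYT4, TMEFF2 and PGC. IGFBP5, a secreted insulin-like growth factor binding protein, was below background on every DMSO array and at least 58.8-fold higher in resistant cells (n = 3 and 3, adjusted p = 8.45e-12). CAMK2N1, an inhibitor of calcium/calmodulin-dependent kinase II, rose by 5.68 ± 0.28 (51.3-fold, adjusted p = 1.64e-07), and COLEC12, a scavenger receptor, by 5.10 ± 0.14 (34.2-fold, adjusted p = 1.69e-09). In the other direction, SYT4, a synaptotagmin of secretory vesicles, fell by 7.35 ± 0.20 (163-fold, adjusted p = 1.69e-09). TMEFF2, a transmembrane protein with follistatin domains, was at least 30.8-fold lower (adjusted p = 1.02e-11) and PGC, the digestive protease progastricsin, at least 30.4-fold lower (adjusted p = 1.97e-09).

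Other genes with large rises in LNCaP were PLA2G2A, a secreted phospholipase A2 (3.93 ± 0.44), SEMA6A, a semaphorin (3.62 ± 0.10), and LRRN1, a leucine-rich repeat membrane protein above background on 2 of the 3 DMSO arrays (3.54 ± 0.15). Rises also included IL1RN, the interleukin-1 receptor antagonist (3.16 ± 0.26), DDC, dopa decarboxylase (3.05 ± 0.24), and ATP1B1, a sodium pump subunit (2.98 ± 0.12). VAV3, a guanine nucleotide exchange factor, was at least 8.77-fold higher (adjusted p = 1.69e-09). Among the falls, UGT2B28, which glucuronidates steroids, dropped by 5.39 ± 0.19. AGR2, a disulfide isomerase of secretory cells above background on 2 of the 3 resistant arrays, dropped by 5.24 ± 0.14 and TARP, read from the T cell receptor gamma locus, dropped by 3.68 ± 0.08. Bounds of at least 9.29-fold for UGT1A1, a bilirubin-conjugating enzyme, 8.61-fold for the transcription factor MAF, 8.25-fold for the cancer-testis antigen CTAG2 and 7.59-fold for RIPOR2 described the remaining falls (adjusted p = 1.69e-09, 1.03e-08, 8.18e-07 and 4.44e-08). UGT2B28, UGT1A1 and CTAG2 have near-identical relatives whose transcripts their probes may also capture. In all, 1653 genes were higher and 1451 lower in resistant LNCaP, 236 and 237 of them by at least 2-fold. With scaling by the 75th percentile 1336 were higher and 1540 lower, so which direction held more genes depended on the normalization. With the LNCaP arrays fitted alone the counts were 2513 and 2341, and other weightings of the arrays gave up to 2563 and 2383.

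Androgen receptor-induced genes fell together in resistant LNCaP. Of 25 measured members, 18 were lower and 1 was higher (19 and 1 adjusted over the list alone), with a median change of -1.96. SLC45A3, the membrane protein prostein (-3.29 ± 0.23), ABCC4, an efflux pump (-3.16 ± 0.15), ALDH1A3, a retinaldehyde dehydrogenase (-3.12 ± 0.09), and ELL2, a transcription elongation factor (-3.09 ± 0.14), had the largest falls. PLPP1, a lipid phosphatase, rose by 0.72 ± 0.17. This was the only list that passed limma's camera test among 22 tested in LNCaP (adjusted p = 2.04e-15), with adjusted p = 0.0882 with an estimated correlation. The list also passed in each of the 9 other ways to part the 6 LNCaP arrays 3 against 3 (adjusted p from 6.16e-05 to 0.00595), each of which keeps part of the real difference by setting 2 arrays of a treatment against 1.

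Genes that androgen receptor activity lowers moved both ways in LNCaP. Of 12 members, 6 were higher and 3 lower (7 and 3 adjusted over the list alone). CAMK2N1, LRRN1 and ACKR3 had the largest rises. UGT2B11 (-2.56 ± 0.21), HES6, a transcriptional repressor (-2.33 ± 0.20), and PRUNE2 (-1.32 ± 0.33) fell (camera adjusted p = 0.265). Among 9 genes of androgen synthesis and inactivation, 5 were higher and 3 lower (5 and 3 adjusted over the list alone). AKR1C3, which makes testosterone from androstenedione, rose by 2.88 ± 0.09 (adjusted p = 5.88e-09), and AKR1C2 rose by 1.08 ± 0.10. The androgen-glucuronidating UGT2B17 rose by 1.69 ± 0.19 and UGT2B15 by 1.05 ± 0.22, and HSD17B4 by 0.50 ± 0.09. SRD5A1, a 5-alpha reductase, dropped by 0.80 ± 0.11, CYP11A1, above background on 1 of the 3 resistant arrays, by 0.64 ± 0.12 and HSD17B6, above background on 2 of the 3, by 0.50 ± 0.13. The list as a whole did not pass (camera adjusted p = 0.373), and paralogs in the AKR1C and UGT2B families may share probe signal.

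MAPK output genes, transcripts that report ERK activity and include its feedback inhibitors, moved both ways in LNCaP, with 2 higher and 4 lower of 13 (3 and 4 adjusted over the list alone, camera adjusted p = 0.792). SPRY4, a sprouty inhibitor, rose by 0.89 ± 0.08 and the immediate early factor EGR1, above background on 2 of the 3 DMSO arrays, by 0.93 ± 0.14. The ERK phosphatase DUSP4 was at least 1.80-fold lower (adjusted p = 4.08e-06) and SPRY1, SPRED1 and SPRED2 dropped by 1.06 ± 0.13, 0.59 ± 0.11 and 0.39 ± 0.10. Among 10 receptor tyrosine kinases and ligands, 2 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.968). HBEGF, an EGF receptor ligand, rose by 0.88 ± 0.21 and ERBB2 by 0.63 ± 0.10. FGFR3 dropped by 0.87 ± 0.24, and IGF1R was at least 1.30-fold lower (adjusted p = 0.000158). Of 11 chemokine receptors and ligands, 2 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.373). Beside ACKR3, CXCR4, above background on 1 of the 3 DMSO arrays, rose by 0.65 ± 0.12. CXCL10 dropped by 3.32 ± 0.09, CCL5 by 1.09 ± 0.11 and the arrestin ARRB1 by 0.59 ± 0.09, and CXCL11, a ligand of CXCR7, was at least 1.34-fold lower (adjusted p = 0.000354).

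Further lists showed member changes in LNCaP without passing camera as lists (adjusted p from 0.178 to 0.846). All 6 cell cycle genes that passed, of 32, were lower (4 adjusted over the list alone, all lower), with camera adjusted p = 0.178, but adjusted p = 0.0247 with the C4-2B set as a block (adjusted p = 0.901 with an estimated correlation). The cell cycle list also passed in 3 of the 9 other ways to part the LNCaP arrays. They included the mitotic kinases PLK1 (-0.58 ± 0.11), AURKB (-0.57 ± 0.17) and BUB1 (-0.57 ± 0.19) and the cyclin CCNB2 (-0.55 ± 0.15). Hypoxia and glycolysis genes had 5 higher and 1 lower of 18 (5 and 2 adjusted over the list alone, camera adjusted p = 0.713). Rises were those of BNIP3L (1.14 ± 0.21), VEGFA (1.02 ± 0.28), PFKFB4 (0.60 ± 0.21) and ADM (0.45 ± 0.11). EGLN3 was at least 1.29-fold higher (adjusted p = 0.000425) and the glucose transporter SLC2A3 at least 1.27-fold lower (adjusted p = 2.36e-05). ATF4 targets, genes of the amino acid stress response, had 4 higher and 1 lower of 17 (6 and 2 adjusted over the list alone, camera adjusted p = 0.373). They were DDIT3 0.79 ± 0.26, ATF4 0.68 ± 0.10, CEBPB 0.49 ± 0.10, PHGDH 0.44 ± 0.09 and MTHFD2 -0.42 ± 0.13. Of 14 chaperone and unfolded protein response genes, XBP1 (1.07 ± 0.12) and DNAJB9 (0.92 ± 0.14) rose and PDIA4 (-0.92 ± 0.12), DNAJC3 (-0.90 ± 0.12) and HSP90B1 (-0.75 ± 0.12) fell. The chaperone list did not pass camera (adjusted p = 0.577), with 3 and 3 members adjusted over the list alone.

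Lipid genes also went both ways in LNCaP. ELOVL5, a fatty acid elongase, dropped by 2.05 ± 0.18 and FADS1, a desaturase, by 0.55 ± 0.10. ELOVL6 rose by 0.47 ± 0.10 and THRSP was at least 1.74-fold higher (adjusted p = 0.000296). This made 2 higher and 2 lower of 12 fatty acid synthesis genes (4 and 4 adjusted over the list alone, camera adjusted p = 0.736). Of 14 cholesterol synthesis genes, MSMO1 (0.46 ± 0.11) was higher and DHCR7 (-0.51 ± 0.10), HMGCS1 (-0.40 ± 0.13) and NSDHL (-0.37 ± 0.10) were lower. Adjusted over the list alone the counts were also 1 and 3 (camera adjusted p = 0.484). Among WNT pathway genes, LEF1, a transcription factor of the pathway, rose by 2.28 ± 0.11 (adjusted p = 1.85e-07), and WNT7B dropped by 0.62 ± 0.16. RNF43, above background only on the resistant arrays, was higher (adjusted p = 0.00921), and no bound is given for its size. The WNT list had 2 higher and 1 lower of 8 (3 and 1 adjusted over the list alone, camera adjusted p = 0.373).

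Members of the stress and inflammatory lists moved both ways in LNCaP. Of 19 interferon-stimulated genes, PARP9 (0.71 ± 0.15), IRF9 (0.58 ± 0.15) and MX1 (0.39 ± 0.13) rose and HERC5 (-0.55 ± 0.18), IFIH1 (-0.49 ± 0.10), IFITM1 (-0.45 ± 0.13) and IFI44 (-0.43 ± 0.11) fell. Interferon counts were 3 and 4 adjusted over the list alone too (camera adjusted p = 0.846). Of 11 NF-kB targets, SOD2 (0.64 ± 0.18) rose and IL32 (-0.70 ± 0.13) and NFKBIA (-0.44 ± 0.12) fell. NF-kB counts were 1 and 2 adjusted over the list alone too (camera adjusted p = 0.577). Of 13 p53 targets, TP53INP1 (0.77 ± 0.15) and SESN1 (0.36 ± 0.11) rose and TP53I3 (-1.14 ± 0.12), ZMAT3 (-0.50 ± 0.10), AEN (-0.48 ± 0.12) and PHLDA3 (-0.43 ± 0.10) fell. The p53 counts were 2 and 4 adjusted over the list alone too (camera adjusted p = 0.413). Of 10 immediate early and heat shock genes, EGR1 and HSP90AA1 (0.35 ± 0.09) rose and HSPH1 (-0.39 ± 0.12) fell (2 and 1, also adjusted over the list alone, camera adjusted p = 0.413).

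Lineage markers of resistant LNCaP shifted in single genes. KRT19, a luminal keratin, dropped by 1.24 ± 0.20, EPCAM by 0.52 ± 0.11, CLDN3 by 0.34 ± 0.10 and SPDEF by 0.30 ± 0.09. GATA2 rose by 0.49 ± 0.16 and FOXA1 by 0.26 ± 0.08. This made 2 higher and 4 lower of 14 luminal genes, also adjusted over the list alone (camera adjusted p = 0.577). SNAI2, a mesenchymal transcription factor, was at least 2.29-fold lower (adjusted p = 4.07e-07), FN1 and VIM dropped by 0.54 ± 0.09 and 0.44 ± 0.11, and TWIST1 rose by 0.44 ± 0.09. These were 1 higher and 3 lower of 6 mesenchymal genes, also adjusted over the list alone (camera adjusted p = 0.373). Of 5 neuroendocrine markers, ENO2 rose by 1.25 ± 0.29 and TUBB3 dropped by 0.79 ± 0.11 (1 and 2 adjusted over the list alone, camera adjusted p = 0.846). Markers of other cell types gave no list shift. VIM and ANXA1 (-0.56 ± 0.10) fell among 5 markers of androgen receptor-negative prostate lines (both also adjusted over the list alone, camera adjusted p = 0.413). None of 3 endothelial markers passed limma's test over all genes or adjusted over the list alone (EGFL7 0.29 ± 0.12, ESAM 0.12 ± 0.13 and VWF -0.14 ± 0.22; 1 at an unadjusted p under 0.05; camera adjusted p = 0.736). Lists with only 2 measured members were not tested as lists. The basal marker LAMB3 rose by 0.69 ± 0.09 while ITGB4 was below background on all 6 LNCaP arrays. The fibroblast marker LUM was at least 1.57-fold higher (adjusted p = 5.68e-06), HLA-DRA among leukocyte markers rose by 0.44 ± 0.08. The estrogen receptor gene ESR1 was at least 1.43-fold higher (adjusted p = 0.00103).

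Among the largest changes in resistant C4-2B were rises of NTS, WNT5A and IGFBP3 and falls of PHLDA1, ADAMTS1 and RND3. NTS, the neuropeptide neurotensin, was below background on both DMSO arrays and at least 78.3-fold higher in resistant cells (n = 2 and 2, adjusted p = 4.73e-07). WNT5A, a secreted WNT ligand above background on 1 of the 2 DMSO arrays, rose by 3.99 ± 0.24 (15.9-fold, adjusted p = 4.83e-06, 3.56 and 4.43 within the pairs), and IGFBP3, an insulin-like growth factor binding protein, by 3.51 ± 0.46 (11.4-fold, adjusted p = 0.000662, 4.92 and 2.10 within the pairs). In the other direction, PHLDA1, a target of ERK signalling, was at least 9.25-fold lower (adjusted p = 6.76e-05), and ADAMTS1, a secreted metalloprotease, fell by 3.35 ± 0.17 (10.2-fold, adjusted p = 2.03e-06, -3.31 and -3.40 within the pairs). RND3, an atypical small GTPase, was at least 6.73-fold lower (adjusted p = 1.13e-05).

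Further rises in C4-2B were those of LRRN1, at least 12.4-fold (adjusted p = 2.03e-06), and ACP3, prostatic acid phosphatase, above background on 1 of the 2 DMSO arrays (3.43 ± 0.17; 3.04 and 3.81 within the pairs). Others were RILPL2 (3.06 ± 0.25; 3.56 and 2.55), GASK1B, at least 7.67-fold (adjusted p = 2.03e-06), and the matrix protein MATN2 (2.89 ± 0.22; 3.20 and 2.57). The semaphorin and VEGF co-receptor NRP1, above background on 1 of the 2 DMSO arrays (2.65 ± 0.18; 2.75 and 2.55) and PLPPR1 (2.59 ± 0.17; 2.36 and 2.82) also rose. The remaining falls were those of ACOX2, a peroxisomal oxidase, at least 6.40-fold (adjusted p = 8.82e-06), and the transcription factor NFIB (-2.77 ± 0.14, with -2.81 and -2.72). The ribosomal RNA probe RNA28SN5 (-2.72 ± 0.61, with -1.20 and -4.24) and ABCC4 (-2.68 ± 0.19, with -2.98 and -2.39) fell too. So did 3 genes above background on 1 of the 2 resistant arrays: the transcriptional repressor ZBTB16 (-2.65 ± 0.15, with -2.88 and -2.42), the CD47 receptor SIRPA (-2.64 ± 0.17, with -3.06 and -2.22) and the aminotransferase AGXT (-2.56 ± 0.24, with -3.23 and -1.88). With the set as a block, the adjusted p of these 20 genes ranged from 8.38e-08 to 0.00205, with the spread still pooled over both lines. On the C4-2B arrays alone, 18 of the 20 passed.

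In all, 1023 genes were higher and 1083 lower in resistant C4-2B, 195 and 230 of them by at least 2-fold. The set as a block gave 1700 and 1805 genes, and 996 and 1109 with array weights by line as well. The C4-2B counts depended on how the spread was estimated. The C4-2B arrays alone, with 2 residual degrees of freedom, gave 76 and 90 genes, among them 14 of the 108 called list members, and array weights gave 319 and 359. Without DMSO replicate 2 the higher genes numbered 640. In simulated data with the larger C4-2B spread, 56.4% of C4-2B calls were false when the arrays varied independently and 9.9% when the arrays of a pair shared their deviations. Only 200 of 10716 genes were changed in these data, and the false share depends on that number. It is therefore no estimate for the real C4-2B calls.

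Androgen receptor-induced genes fell in resistant C4-2B as well, and cell cycle genes rose. Of 25 androgen receptor-induced members, all 16 that passed were lower (18 adjusted over the list alone, all lower), with a median of -0.93, or -0.75 with members below background at their bound. ABCC4, ZBTB16, PMEPA1, a TGF-beta pathway inhibitor (-2.32 ± 0.15, adjusted p = 6.44e-06, -2.52 and -2.11 within the pairs), and KLK2, a kallikrein protease (-2.12 ± 0.25, adjusted p = 0.000302, -2.79 and -1.46), had the largest falls. The list passed camera (adjusted p = 3.75e-11; adjusted p = 0.101 with an estimated correlation), with medians of -1.09 and -0.78 within the pairs and adjusted p = 3.54e-10 with the set as a block. Of 32 cell cycle genes, all 22 that passed were higher (29 adjusted over the list alone, all higher), with a median of 0.89. TYMS, thymidylate synthase (1.47 ± 0.25), the replication factors MCM4 (1.43 ± 0.34) and GINS2 (1.38 ± 0.30), and RRM2, a ribonucleotide reductase subunit (1.27 ± 0.28, 0.62 and 1.93 within the pairs), led the list. It passed camera (adjusted p = 7.74e-13; adjusted p = 0.359 with an estimated correlation), with medians of 0.91 and 0.70 within the pairs and adjusted p = 4.83e-17 with the set as a block.

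Hypoxia and glycolysis genes fell in resistant C4-2B: 8 of 18 were lower (10 adjusted over the list alone), with a median of -0.61, or -0.53 at bounds. ANKRD37, a hypoxia-inducible gene (-1.66 ± 0.31), the angiogenic factor VEGFA (-1.37 ± 0.35), the glycolytic enzyme ALDOA (-1.36 ± 0.21) and the glucose transporter SLC2A1 (-0.94 ± 0.19, -1.41 and -0.46 within the pairs) had the largest falls. Against LNCaP DMSO arrays, the list lay higher in C4-2B DMSO arrays (median 0.92) and at a median of 0.07 in resistant C4-2B arrays. The resistant arrays differed, with mean levels of -0.21 and 0.49, against 0.70 and 0.89 on the C4-2B DMSO arrays. Line and array set cannot be told apart in these values. The list passed camera (adjusted p = 7.88e-05; adjusted p = 0.433 with an estimated correlation), with medians of -0.93 and -0.32 within the pairs and adjusted p = 1.03e-05 with the set as a block. WNT pathway genes rose, with 6 of 8 higher, also adjusted over the list alone, and a median of 0.71, or 0.64 at bounds. Beside WNT5A, the WNT antagonist DKK1 was at least 2.89-fold higher (adjusted p = 0.0051), LEF1, above background on 1 of the 2 DMSO arrays, rose by 1.02 ± 0.14, and the feedback inhibitor RNF43 was at least 1.38-fold higher (adjusted p = 0.00214). The WNT list passed camera (adjusted p = 7.88e-05; adjusted p = 0.0912 with an estimated correlation), with medians of 0.85 and 0.71 within the pairs and adjusted p = 0.000135 with the set as a block.

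Fatty acid synthesis genes fell in resistant C4-2B, with 6 lower and 1 higher of 12 (9 and 1 adjusted over the list alone) and a median of -0.54. FASN, fatty acid synthase, fell by 1.44 ± 0.26, the desaturase SCD by 1.03 ± 0.26, the transcription factor SREBF1 by 1.01 ± 0.18 and ACACA, acetyl-CoA carboxylase, by 0.98 ± 0.14. The elongase ELOVL6 rose by 0.91 ± 0.12. For this list too the C4-2B DMSO arrays lay above LNCaP DMSO arrays (median 0.57, 95% bootstrap interval -0.29 to 1.15) and resistant C4-2B arrays closer to them (-0.13, interval -0.62 to 0.75). Both intervals resample genes, which are not independent, and not arrays. The list passed camera (adjusted p = 0.00196; adjusted p = 0.338 with an estimated correlation), with medians of -0.74 and -0.43 within the pairs and adjusted p = 0.000163 with the set as a block. MAPK output genes were lower, with 4 of 13 passing (6 adjusted over the list alone) and a median of -0.25, or -0.13 at bounds. The falls were those of PHLDA1, the feedback inhibitor SPRY1 (-1.57 ± 0.16, adjusted p = 0.00013, -1.97 and -1.16 within the pairs), the cyclin CCND1 (-0.50 ± 0.15, -0.80 and -0.20 within the pairs) and IER3 (-0.45 ± 0.14). This list passed camera (adjusted p = 0.00975; adjusted p = 0.183 with an estimated correlation), with medians of -0.35 and -0.20 within the pairs and adjusted p = 0.0106 with the set as a block. The call was lost without PHLDA1 and SPRY1 together (adjusted p = 0.138), with a median of -0.24 over the other 11 members, a test chosen after the values were seen.

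Of 13 p53 targets in C4-2B, 5 were lower, also adjusted over the list alone, with a median of -0.35. They were the stress cytokine GDF15 (-2.13 ± 0.53), the cell cycle inhibitor CDKN1A (-1.84 ± 0.38), AEN (-0.75 ± 0.15), TP53I3 (-0.75 ± 0.15) and PHLDA3 (-0.58 ± 0.12). The list passed camera (adjusted p = 0.0137; adjusted p = 0.433 with an estimated correlation), with medians of -0.19 and -0.68 within the pairs and adjusted p = 0.0083 with the set as a block. Of 17 ATF4 targets, 5 were lower, also adjusted over the list alone, with a median of -0.34. They were ATF3 (-1.24 ± 0.34), DDIT3 (-1.23 ± 0.32), TRIB3 (-1.15 ± 0.24), PSAT1 (-0.59 ± 0.16, -0.996 and -0.194 within the pairs) and CEBPB (-0.56 ± 0.12). This list passed camera (adjusted p = 0.0165; adjusted p = 0.629 with an estimated correlation), with medians of -0.53 and -0.10 within the pairs and adjusted p = 0.0117 with the set as a block. Of 10 immediate early and heat shock genes, the heat shock genes HSPH1 (-0.62 ± 0.15, -0.24 and -1.01 within the pairs) and HSPA8 (-0.44 ± 0.12) were lower (5 adjusted over the list alone, all lower). The heat shock list had a median of -0.51 (camera adjusted p = 0.0128; adjusted p = 0.248 with an estimated correlation; -0.42 and -0.45 within the pairs; adjusted p = 0.00356 with the set as a block). Of 14 luminal genes, SPDEF, a luminal transcription factor (-1.31 ± 0.11), KRT19 (-1.17 ± 0.25) and CLDN7, a tight junction protein (-1.09 ± 0.12), were lower, also adjusted over the list alone. The luminal list had a median of -0.20 (camera adjusted p = 0.0137; adjusted p = 0.433 with an estimated correlation; -0.19 and -0.18 within the pairs; adjusted p = 0.0115 with the set as a block).

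The other lists did not pass camera in C4-2B (adjusted p from 0.236 to 0.892). Of 12 androgen receptor-repressed genes, LRRN1, ACKR3, UGT2B15 (1.18 ± 0.27, 0.39 and 1.97 within the pairs) and UGT2B17 (0.94 ± 0.23, 0.26 and 1.62) rose. HES6 dropped by 1.02 ± 0.25 and BCHE was at least 1.23-fold lower (adjusted p = 0.0104). These were 4 higher and 2 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.498). Of 9 genes of androgen synthesis and inactivation, UGT2B15, UGT2B17 and HSD17B4 (0.43 ± 0.11) rose and SRD5A1 (-0.54 ± 0.13) fell, also adjusted over the list alone (camera adjusted p = 0.466). Of 10 receptor tyrosine kinases and ligands, FGFR3 dropped by 2.00 ± 0.29 and TGFA rose by 0.53 ± 0.14 (0.80 and 0.26 within the pairs), also adjusted over the list alone (camera adjusted p = 0.722). Of 11 chemokine receptors and ligands, ACKR3 rose and its ligand gene CXCL12 was at least 1.16-fold lower (adjusted p = 0.0288), also adjusted over the list alone (camera adjusted p = 0.892). Of 5 neuroendocrine markers, NTS rose and TUBB3 (-0.98 ± 0.14) fell, also adjusted over the list alone (camera adjusted p = 0.892). VIM, the intermediate filament vimentin, dropped by 2.18 ± 0.13 (adjusted p = 5.53e-06, -2.10 and -2.27 within the pairs) and TGFBI was at least 1.05-fold lower (adjusted p = 0.0369). These were the changes, also adjusted over the list alone, among both the 6 mesenchymal genes (camera adjusted p = 0.425) and the 5 markers of androgen receptor-negative lines (camera adjusted p = 0.329).

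Of 19 interferon-stimulated genes in C4-2B, IFIT1 (1.17 ± 0.19) and IFITM1 (0.57 ± 0.16) rose and IRF7 (-1.15 ± 0.23), IFIH1 (-0.80 ± 0.12), BST2 (-0.83 ± 0.20) and HERC5, above background on 1 of the 2 resistant arrays (-1.70 ± 0.22), fell. Interferon counts were 2 and 4 adjusted over the list alone too (camera adjusted p = 0.892). Of 11 NF-kB targets, SOD2 (0.82 ± 0.22) rose and IL32 (-1.57 ± 0.16), NFKBIA (-0.77 ± 0.15) and NFKB2 (-0.75 ± 0.13) fell, also adjusted over the list alone (camera adjusted p = 0.329). Of 14 chaperone and unfolded protein response genes, HSPA5, the chaperone BiP, dropped by 1.10 ± 0.21 and CRELD2 rose by 0.56 ± 0.15, also adjusted over the list alone (camera adjusted p = 0.892). Of 14 cholesterol synthesis genes, LSS (-0.56 ± 0.18) and DHCR7 (-0.47 ± 0.12) fell (1 adjusted over the list alone, camera adjusted p = 0.722). None of 3 endothelial markers passed limma's test, also adjusted over the list alone (EGFL7 -0.42 ± 0.15, ESAM -0.28 ± 0.16 and VWF -0.46 ± 0.27; 1 at an unadjusted p under 0.05; camera adjusted p = 0.236). Of the pairs of genes too few to test as lists, NR3C2, the mineralocorticoid receptor gene, was at least 1.99-fold lower (adjusted p = 0.000331). The fibroblast marker COL1A1 had a value of -0.17 ± 0.15 (adjusted p = 0.484) and HLA-DRA of -0.20 ± 0.10 (adjusted p = 0.186). ESR1, LUM and LAMB3 were below background on all 4 C4-2B arrays, CD79A was below background on both resistant arrays, and ITGB4 had a value of -0.09 ± 0.15 (adjusted p = 0.702).

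**Figure D2:**
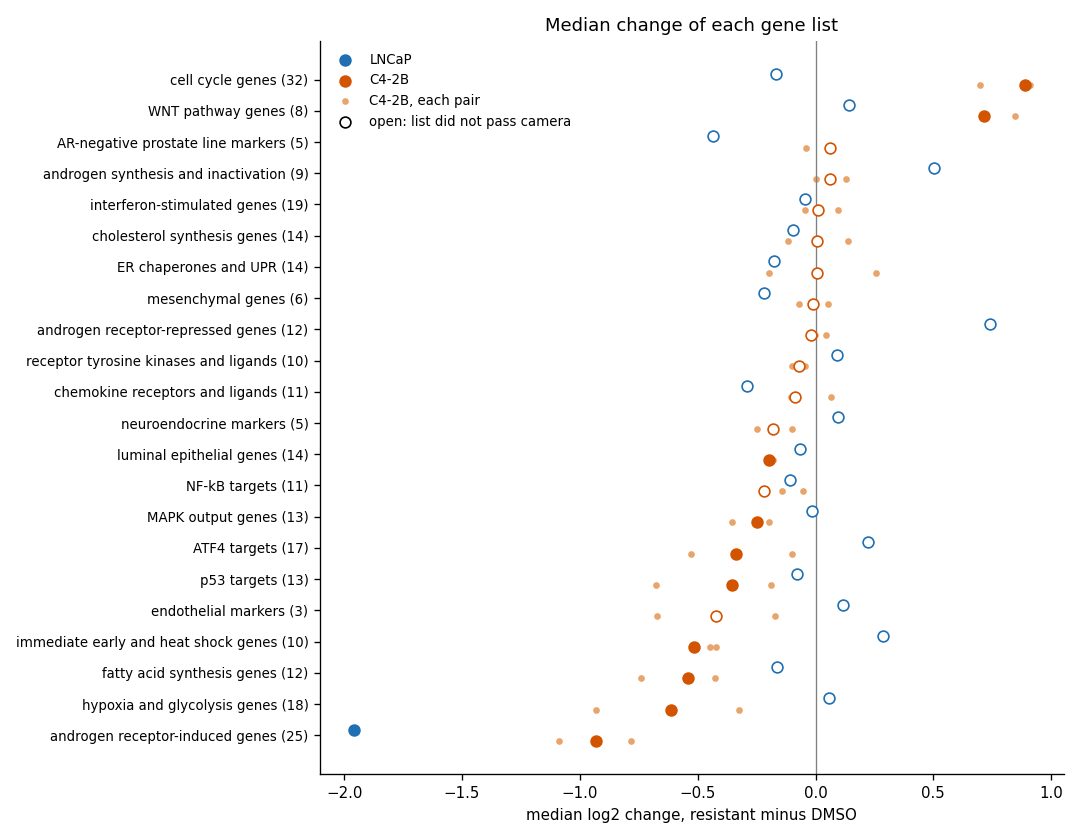
Median log2 change, resistant minus DMSO, of each gene list tested (vertical axis, with the number of measured members) in LNCaP and in C4-2B (large points; filled where the list passed camera) and within each C4-2B pair of arrays (small points). The androgen receptor-induced list lies at -1.96 in LNCaP and -0.93 in C4-2B, and the cell cycle list at -0.17 and 0.89.

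Genes that changed in both lines overlapped beyond the number that independent lists would share. LRRN1, above background on 2 of the 3 LNCaP DMSO arrays, rose by 3.54 in LNCaP and at least 12.4-fold in C4-2B. MATN2, above background on 1 of the 3 LNCaP DMSO arrays, rose by 2.88 ± 0.18 and 2.89 ± 0.22 and PLA2G2A by 3.93 ± 0.44 and 2.34 ± 0.54. The synaptic adhesion gene NLGN1, above background on 1 of the 3 LNCaP DMSO arrays, rose by 2.37 ± 0.19 and 2.25 ± 0.23. The testis bromodomain gene BRDT was at least 4.13-fold and at least 3.23-fold higher (adjusted p = 3.05e-07 and 1.47e-05). The largest shared falls, in LNCaP and C4-2B, were those of ABCC4 (-3.16 and -2.68), PMEPA1 (-3.01 ± 0.12 and -2.32 ± 0.15), the kinase STK39 (-2.99 ± 0.13 and -2.06 ± 0.16) and KLK2 (-2.05 ± 0.20 and -2.12 ± 0.25). PGC was at least 30.4-fold lower in LNCaP and fell by 2.01 ± 0.18 in C4-2B, where it was above background on 1 of the 2 resistant arrays. In all, 312 genes were higher in both lines against 157.8 for independent lists (Fisher's exact p = 7.31e-38, odds ratio 2.73). For lower genes, 273 were lower in both against 146.6 (Fisher's exact p = 9.81e-28, odds ratio 2.42). Another 142 and 99 genes went opposite ways against 167.1 and 138.5. These tests run across genes, which are not independent replicates, and the lines have separate controls. As sets, the genes called in C4-2B moved the same way in LNCaP (limma's fry, adjusted p = 0.00182 for higher and adjusted p = 0.00454 for lower), but by medians of only 0.11 and -0.056. Those called in LNCaP moved the same way in C4-2B (adjusted p = 0.00182 and adjusted p = 0.000323), by medians of 0.072 and -0.085. Over all genes the changes correlated weakly (Pearson r = 0.217, Spearman rho = 0.12, across genes), and 53.3% had the same sign. The shared counts were 48 and 57 when each line was fitted alone, 152 and 159 with array weights, and 536 and 525 with the set as a block. With the block and array weights by line they were 374 and 381.

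**Figure D3:**
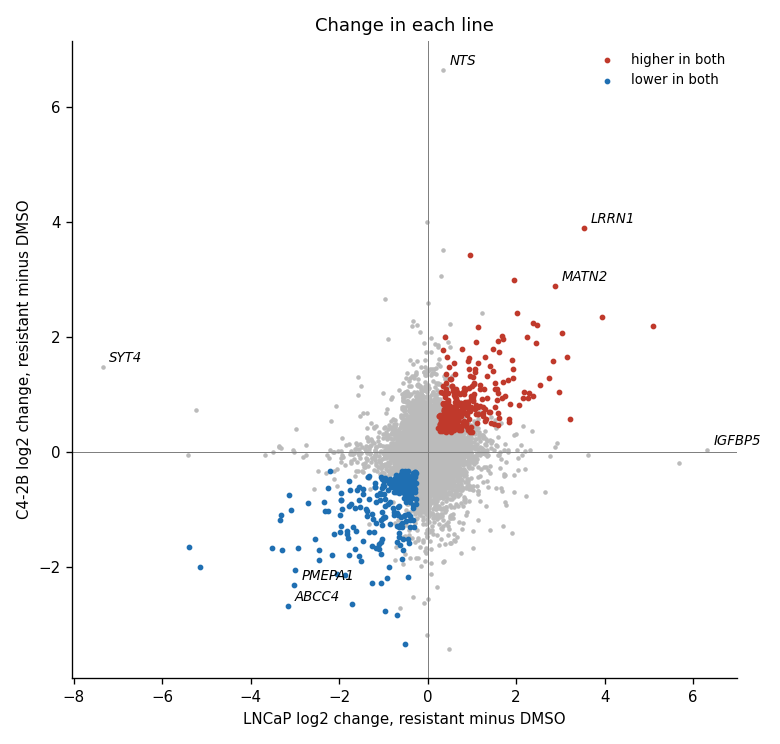
Log2 change, resistant minus DMSO, in LNCaP (horizontal axis) and C4-2B (vertical axis) for each of the 10716 genes tested (points); coloured points are the 312 genes higher and the 273 genes lower in both lines. SYT4 went opposite ways in the lines, NTS passed only in C4-2B and IGFBP5 only in LNCaP, and LRRN1, MATN2, ABCC4 and PMEPA1 genes that changed in both.

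The size or direction of change differed between the lines for many genes. SYT4 fell in LNCaP and rose by 1.48 ± 0.25 in C4-2B (difference of C4-2B minus LNCaP changes 8.82 ± 0.32, adjusted p = 8.5e-08). CAMK2N1 rose in LNCaP and changed by -0.20 in C4-2B (difference -5.89 ± 0.44). AGR2, above background on 1 of the 2 C4-2B DMSO arrays, had a difference of 5.95 ± 0.23, and MAP1B, a microtubule-associated protein that rose by 2.66 ± 0.19 in LNCaP and was above background on 1 of the 2 resistant C4-2B arrays, of -3.35 ± 0.30. In C4-2B DMSO cells CAMK2N1 was already higher and AGR2 already lower than in LNCaP DMSO cells, as given below. For these genes the difference does not separate starting level from response. NTS, TMEFF2 and WNT5A also had high differences and IGFBP5, PHLDA1 and SEMA6A low ones, but each was below background on every array of at least 1 group, so that size and rank measure signal against background. TMEFF2, IGFBP5 and SEMA6A were below background on all 4 C4-2B arrays, which leaves open whether C4-2B responded differently. Among the differing genes, 456 of 2449 were below background throughout at least 1 group. In all, the difference was positive for 1133 genes and negative for 1316. With the set as a block 3941 genes differed, and with array weights 1418.

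By list, cell cycle genes rose in C4-2B relative to LNCaP (23 of 32 with a positive difference, median 1.03; adjusted p = 1.04e-11 by camera, 0.511 as adjusted p with an estimated correlation, 7.07e-16 with the set as a block). AURKB (1.58 ± 0.27) and RRM2 (1.58 ± 0.36) were examples. The androgen receptor-induced list fell less in C4-2B (10 positive and 3 negative differences of 25, median 0.47, adjusted p = 0.00274; adjusted p = 0.511 with an estimated correlation; 0.00717 with the set as a block). ALDH1A3 (2.37 ± 0.14) had among the most positive differences, as had ELL2, and KLK4 (-1.58 ± 0.36), PTGER4 and ZBTB16 (-0.93 ± 0.20) the negative ones. ELL2 and PTGER4 were below background on both resistant C4-2B arrays and ZBTB16 on 1 of the 2. Differences were negative for hypoxia and glycolysis genes (7 of 18, median -0.63, adjusted p = 0.0019; adjusted p = 0.787 with an estimated correlation; 0.000227 with the set as a block). VEGFA (-2.39 ± 0.45) and BNIP3L (-1.87 ± 0.34) were examples. ATF4 targets (6 of 17, median -0.46, adjusted p = 0.018; adjusted p = 0.787 with an estimated correlation; 0.0131 with the set as a block), led by DDIT3 (-2.02 ± 0.42) and TRIB3 (-1.68 ± 0.32), also had negative differences. So did immediate early and heat shock genes (2 of 10, EGR1, below background on both resistant C4-2B arrays, and HSP90AA1 -0.61 ± 0.14, median -0.72, adjusted p = 0.0119; adjusted p = 0.511 with an estimated correlation; 0.00311 with the set as a block). Adjusted over the list alone, the counts were 29 for cell cycle genes, 10 and 5 for androgen receptor-induced genes, 9 for hypoxia and glycolysis genes, 7 for ATF4 targets and 4 for immediate early and heat shock genes. MAPK output genes did not differ as a list (median -0.41, camera adjusted p = 0.199).

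**Figure D4:**
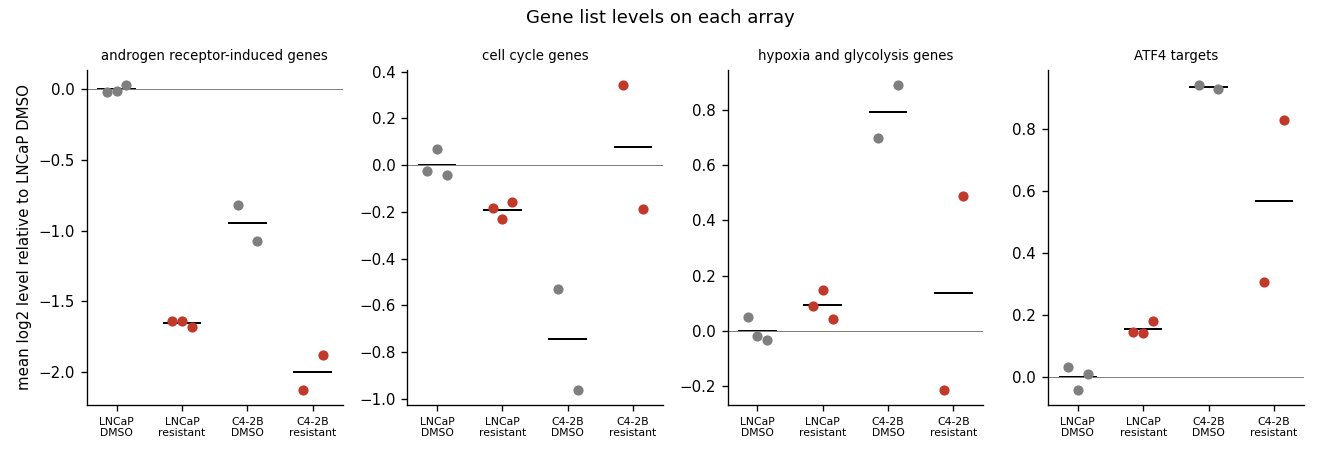
Mean log2 level of 4 gene lists (panels) on each of the 10 arrays (points), relative to the LNCaP DMSO mean of the same genes (vertical axis, log2 units), by group (horizontal axis), with the group mean as a bar. The cell cycle list lies below LNCaP DMSO in C4-2B DMSO arrays and on either side of it in the C4-2B resistant arrays (0.34 and -0.19), and the androgen receptor-induced list falls in both lines.

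The DMSO controls gave the starting difference between the lines. CAMK2N1 was higher in C4-2B DMSO than in LNCaP DMSO cells by 5.48 ± 0.31 (44.6-fold, n = 2 and 3, adjusted p = 2.46e-07), as were the cancer-testis genes PAGE1, above background on 1 of the 3 LNCaP DMSO arrays (5.41 ± 0.19) and TEX19 (5.05 ± 0.33). CT45A3 was higher by at least 26.1-fold (adjusted p = 7.78e-11), and LIN7A, a scaffold protein, at least 28.3-fold (adjusted p = 2.04e-10). GSTA1, a glutathione transferase, was at least 40.2-fold lower in C4-2B (adjusted p = 1.1e-10), and TARP at least 42.7-fold (adjusted p = 3.33e-11). TMEFF2 was lower by at least 32.5-fold (adjusted p = 3.33e-11) and the metalloprotease MMP7 at least 28.6-fold (adjusted p = 1.93e-10). AGR2, above background on 1 of the 2 C4-2B DMSO arrays, was lower by -5.38 ± 0.16. ACKR3 was higher in C4-2B DMSO cells by 1.28 ± 0.37 (2.43-fold, adjusted p = 0.0124). In all, 3004 genes were higher and 2884 lower in C4-2B DMSO arrays. By the same inference from the processed values, the lines were in separate array sets, so line and set cannot be told apart here.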

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

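The tests on the cell cycle and androgen receptor-induced lists, and the count of genes over other splits of the LNCaP arrays, were chosen only after the results were seen. All differences here are the C4-2B change minus the LNCaP change in log2 units, each past limma's test of the difference itself, and they stand out because the measured change differed between related lines. The lines were selected at doses that differ 10-fold by either source, so line and dose cannot be told apart. Of the 121 genes named here, 47 were below background on every array of at least 1 group, and their values measure signal against background and leave open whether the lines responded differently.

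The difference passed for 2449 genes. The 5 highest values were SYT4 8.82, NTS 6.30, AGR2 5.95, TMEFF2 5.36 and WNT5A 4.01. Others that fell in LNCaP or rose in C4-2B were UGT2B28 3.74, TARP 3.63, NRP1 3.61, UGT1A1 3.49, RIPOR2 3.46, MAF 3.44, CXCL10 3.39, IGFBP3 3.17, PGC 3.14, MMP7 3.08, PLPPR1 2.57, RILPL2 2.75, ACP3 2.46, UGT2B11 1.92, CTAG2 1.84, DKK1 1.78 and GASK1B 1.03. The 5 lowest values were IGFBP5 -6.28, CAMK2N1 -5.89, PHLDA1 -3.92, SEMA6A -3.68 and MAP1B -3.35. Other negative values were those of RND3 -3.17, COLEC12 -2.91, ADAMTS1 -2.84, AKR1C3 -2.80, VAV3 -2.66, AGXT -2.56, SIRPA -2.55, ACOX2 -2.14, ATP1B1 -1.94, NFIB -1.80, TEX19 -1.68, IL1RN -1.50, LIN7A -0.68 and CT45A3 -0.67.

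Androgen receptor-induced genes had a median difference of 0.47, with ALDH1A3 2.37, ELL2 2.07, KLK3 1.76, SLC45A3 1.57, PMEPA1 0.69, PTGER4 -1.09, ZBTB16 -0.93 and KLK4 -1.58. Of these, KLK3, ELL2 and PTGER4 were below background on both resistant C4-2B arrays. Their values measure signal against background, and the KLK3 change cannot be compared between the lines. The cell cycle list had a median of 1.03, with AURKB 1.58, RRM2 1.58, TYMS 1.52, BUB1 1.46, GINS2 1.46, MCM4 1.44, CCNB2 1.32 and PLK1 0.85. Hypoxia and glycolysis genes had -0.63, with VEGFA -2.39, BNIP3L -1.87, ALDOA -1.34, SLC2A1 -0.96 and EGLN3 -0.60. ATF4 targets had -0.46, with DDIT3 -2.02, TRIB3 -1.68, CEBPB -1.05, ATF4 -0.89 and PSAT1 -0.82. Immediate early and heat shock genes had -0.72, with EGR1 -1.18 and HSP90AA1 -0.61.

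Signalling genes differed too, with HBEGF -1.29, SPRY4 -0.86, IER3 -0.75, CXCR4 -0.71, ERBB2 -0.56, DUSP4 1.10, IGF1R 0.91, SPRED1 0.67, CXCL11 0.68, CCL5 1.44, ARRB1 0.50 and STK39 0.93. Steroid, lipid and WNT genes gave AKR1C2 -1.04, HES6 1.30, NR3C2 -0.79, ESR1 -0.97, SREBF1 -1.41, THRSP -1.38, FASN -1.02, ACACA -0.89, MSMO1 -0.74, ELOVL5 1.45, LEF1 -1.26 and WNT7B 0.90. Stress, interferon and inflammatory genes gave HSPA5 -1.12, XBP1 -0.84, DNAJB9 -1.07, CRELD2 0.83, DNAJC3 0.86, HSP90B1 0.76, PDIA4 1.15, GDF15 -2.21, SESN1 -0.64, IRF7 -1.65, HERC5 -1.15, BST2 -0.79, IFIT1 0.95, IFITM1 1.02, IL32 -0.87 and NFKB2 -0.57. Lineage and cell type markers gave VIM -1.75, SNAI2 1.68, FN1 0.78, TGFBI -0.56, ANXA1 0.62, CLDN7 -1.18, SPDEF -1.01, EPCAM 0.58, LAMB3 -0.66, LUM -1.10, EGFL7 -0.71 and HLA-DRA -0.63.

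Probes without a gene symbol, which entered no comparison of the report, also changed: of 3552 tested, 741 passed in LNCaP and 444 in C4-2B.

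Cell cycle genes rose in C4-2B resistant arrays. The list rose within both C4-2B pairs, with the smaller median at 0.70 and all 32 members higher in both, so the rise did not rest on a single pair. A shift shared by the DMSO and resistant array of a set cancels in this change, so the pairs are no test of such a shift. The background correction or scaling was argued against, since the lowest median under the alternatives was 0.59. The list also lay lower in C4-2B DMSO than in LNCaP DMSO arrays by a median of -0.74 (95% bootstrap interval -0.97 to -0.44), while C4-2B resistant arrays lay 0.07 from LNCaP DMSO arrays (95% bootstrap interval -0.16 to 0.34, with mean levels of 0.34 and -0.19 on the single arrays). These intervals resample genes, which are not independent, and not arrays. A candidate explanation is slow growth of the C4-2B DMSO cultures, which these arrays cannot decide without a measurement of growth or cell cycle phase. Because the lines were in separate array sets, as inferred from the processed values, line and set cannot be told apart in this comparison, and an effect of resistance on proliferation stays open.

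Androgen receptor-induced genes fell less in C4-2B than in LNCaP. A lower starting level in C4-2B, leaving little signal to lose, might account for this: the median difference was 0.39 over the 14 members well above background in C4-2B DMSO arrays (95% bootstrap interval -0.22 to 0.75) and 1.12 over the other 11. The interval of the first includes 0 as well as the value of the whole list, so this stays open, as does a difference between the lines in androgen receptor activity. That interval resamples genes, which are not independent, and not arrays.

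Among the 10 splits of the 6 LNCaP arrays into 3 and 3, 1 split, the real one, gave as many genes by limma, 3104 against at most 0 in the others (82 to 139 genes at an unadjusted p under 0.05), and all 10 splits gave at least as many gene lists, 1 against at most 2. The splits are too few for a share under 0.05.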

How the results depend on the processing

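The C4-2B set as a block, array weights by line and their combination were tests chosen only after the data were seen. No value reversed its sign. The balance of counts did turn with 75th percentile scaling, to 1336 higher and 1540 lower genes in LNCaP (46.5% higher, against 53.3%), 257 and 284 shared genes, and 46.3% higher between the DMSO lines (against 51%). Genes differing between the lines were 50.2% higher (against 46.3%). C4-2B turned to 994 higher and 966 lower with the authors' processed values. The shared counts turned under several settings. Among these were the own arrays, array weights, array weights by line with and without the set as a block, and the 2-fold threshold. Of 6030 values of other results under alternatives, 5622 kept their label and 408 were weaker, meaning that the call was lost with the sign kept. No slide was recorded, so a slide block was not run. Signal over background limits dim genes, and 2 arrays per group limit C4-2B.

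The ACKR3 change in C4-2B kept its size but not its call without the detection filter (1.58, adjusted p = 0.0503) and on the line's own arrays (1.58, adjusted p = 0.211). Leaving out single arrays, it ranged from 0.71 (without C4-2B DMSO replicate 2) to 2.44 (without C4-2B DMSO replicate 1), and the call was lost without C4-2B resistant replicate 1 (1.32, adjusted p = 0.111). In LNCaP it ranged from 2.82 to 2.86. C4-2B genes ranged from 640 (without DMSO replicate 2) to 1307 higher and from 747 to 1354 lower, and C4-2B lists from 7 to 10. LNCaP genes ranged from 1220 to 1914 higher and from 1024 to 1716 lower, and LNCaP lists stayed at 1. Genes differing between the lines ranged from 1782 to 3149 and between the DMSO lines from 4954 to 6272, and shared genes from 220 to 340 higher and from 190 to 319 lower. Where a group was left with 1 array, that array is assumed to vary like the other groups.

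On each line's own arrays, 2513 and 2341 genes passed in LNCaP (1653 and 1451 over all arrays), 76 and 90 in C4-2B (1023 and 1083), 48 and 57 in both (312 and 273), and 2 LNCaP lists (1). Alone, the C4-2B arrays left 2 residual degrees of freedom, against 6. Array weights gave 2563 and 2380, 319 and 359, 152 and 159, and 1418 genes differing between lines (2449). By line, the weights gave 2547 and 2365, 316 and 359, 149 and 159, and 1399. The set as a block gave 1700 and 1805 C4-2B genes, 536 and 525 shared, 3941 differing and 2 LNCaP lists, the other being cell cycle genes (adjusted p = 0.0247). With weights by line as well it gave 2556 and 2383 LNCaP genes, 996 and 1109 C4-2B genes, 374 and 381 shared genes and 2 LNCaP lists. The cause of these moves was not tested.

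With the replicate number as a block, which does not pair the LNCaP arrays (r = -0.0871, 0.0209 and -0.0929 between same-numbered arrays; 1 of 3 matched its own number best), 2056 and 1903 LNCaP genes, 1443 and 1559 C4-2B genes, 431 and 414 shared genes, 3439 differing genes, 2 LNCaP lists and 10 C4-2B lists passed. In C4-2B r was 0.537, a single value. The deviations of 2 arrays from their group mean are opposite, so both pairs give the same r by construction.

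Stricter thresholds lowered counts by construction. At least 2-fold left 236 and 237 LNCaP genes, 195 and 230 C4-2B genes, 798 differing, 1328 between the DMSO lines, and 48 and 55 shared. An adjusted p under 0.01 left 1019 and 826, 440 and 508, 1085 differing, and 142 and 119 shared. Camera with an estimated correlation passed 0 LNCaP and 0 C4-2B lists (1 and 4 at an unadjusted p under 0.05), and fry, which asks whether a list moves and not whether it moves more than other genes, passed 6 LNCaP lists (14 in C4-2B).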

Other observations

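The list and symbol family tests between the DMSO lines were chosen only after the data were seen. The starting states of the lines differed by gene group, though line and the array set inferred from the processed values cannot be told apart in these values. Androgen synthesis and inactivation genes were lower in C4-2B DMSO arrays in 8 of 9 cases (median -0.98, camera adjusted p = 0.00129, adjusted p = 0.569 with an estimated correlation). AKR1C2 was at least 14.1-fold lower, UGT2B17 and UGT2B15 had -3.27 ± 0.21 and -2.67 ± 0.25, and HSD17B6 was higher by 1.25 ± 0.15. Of 25 androgen receptor-induced genes, 14 were lower, for example ELL2 (-3.36 ± 0.15) and SLC45A3 (-2.74 ± 0.26), with a median of -0.73 (camera adjusted p = 0.00129, adjusted p = 0.569 with an estimated correlation). The 5 higher ones were TSC22D3 (1.49 ± 0.17), KLK15 (1.36 ± 0.20), KLK4 (0.96 ± 0.26), NDRG1 (0.66 ± 0.25) and PTGER4 (0.44 ± 0.12). All 21 of 32 cell cycle genes that passed were lower (median -0.74, camera adjusted p = 0.000343, adjusted p = 0.569 with an estimated correlation), led by GINS2 (-2.09 ± 0.28) and TYMS (-2.04 ± 0.23). Interferon-stimulated genes were lower in 13 of 19 cases (median -1.19, camera adjusted p = 0.000717, adjusted p = 0.569 with an estimated correlation). IFI44 was at least 4.69-fold lower and IFIT1 had -2.71 ± 0.17, whereas IRF7 (1.89 ± 0.21) and BST2 (1.43 ± 0.18) were higher.

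Hypoxia and glycolysis genes were higher in C4-2B DMSO arrays in 11 of 18 cases and lower in 1, ADM (-0.32 ± 0.12), with a median of 0.92 (camera adjusted p = 0.0127, adjusted p = 0.569 with an estimated correlation). P4HA1 (2.39 ± 0.29) and PFKP (1.65 ± 0.27) were examples. ATF4 targets were higher in 11 of 17 cases and lower in 1, SLC7A11 (-0.54 ± 0.16), with a median of 0.57 (camera adjusted p = 0.00129, adjusted p = 0.569 with an estimated correlation). The amino acid transporter SLC7A5 (3.91 ± 0.20) and DDIT3 (2.27 ± 0.30) were examples. NF-kB targets were lower in 6 of 11 cases (median -0.85, camera adjusted p = 0.0453, adjusted p = 0.569 with an estimated correlation), for example CCL2 (-1.98 ± 0.35), and 2 were higher, ICAM1 and TNFAIP2, both below background on every LNCaP DMSO array. Every call was therefore lost with an estimated correlation. Among 164 families of genes sharing a symbol stem, 2 passed. They were UGT enzymes, with 8 of 9 lower and 1 higher, UGT8 (0.60 ± 0.12; median -3.27, camera adjusted p = 0.00142), and PSMB proteasome subunits, with 10 of 10 lower (median -0.52, camera adjusted p = 0.00905). Both were lost with an estimated correlation (adjusted p = 0.958 with an estimated correlation).

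Neighbouring genes shifted together. Between genes 10 places apart the correlation was 0.0717 for the difference between the DMSO lines, 0.0591 for the LNCaP change and 0.0576 for the C4-2B change, against at most 0.0318, 0.0327 and 0.031 in 1000 shuffled gene orders (one-sided permutation p = 0.001 for each, the smallest these shuffles can give). These correlations run across genes, which are not independent replicates. Windows of 25 neighbouring genes were compared with 200 shuffled orders, in which the highest window median lay 0.71, 0.41 and 0.42 from the median of all genes. Windows beyond these values, joined where they overlapped or adjoined, made 5 runs between the DMSO lines, 7 in LNCaP and 3 in C4-2B. The median over a joined run can be smaller than that of its windows. Among them were a higher run on chromosome 4 from TRMT10A to AP1AR in LNCaP (34 genes, median 0.43) and a lower run on chromosome 4 from MAD2L1 to LRBA in C4-2B DMSO arrays (45 genes, median -0.67).

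The longest run was on chromosome 9, from SH3GLB2 to ARRDC1: 100 of its 106 genes were lower in resistant C4-2B, with a median of -0.49 (95% bootstrap interval -0.54 to -0.44), and 61 passed, all lower, while its median in LNCaP was 0.03. The run was picked for its low windows in this same C4-2B comparison. Its count, calls and interval therefore restate that choice and give no separate support. The interval, like those below, also treats neighbouring genes as independent. The smaller change within a pair was -0.45. This cannot exclude the array sets, since the run was picked on these same pairs. A shift shared by the DMSO and resistant array of a set also cancels in the change. The background correction and scaling were argued against, since the smallest change on the same arrays under the alternatives was -0.30. A bias against gene-dense chromosomes as large as the shift of the run was argued against too. Chromosome 19 had a median of -0.084 (95% bootstrap interval -0.11 to -0.06). Yet 461 of its 742 genes were lower, so a smaller bias of this kind stays open. The other 325 chromosome 9 genes were lower too, 246 of them, with a median of -0.22 (95% bootstrap interval -0.26 to -0.18), so the shift was not limited to the run. Over the run, C4-2B DMSO arrays lay above LNCaP DMSO arrays by a median of 0.20 (95% bootstrap interval 0.06 to 0.35, with 38 of 106 genes lower). The run was picked for a low change against these same C4-2B DMSO arrays, which favours a high value here. No higher starting level can therefore be concluded, and line and array set cannot be told apart either. A lower copy number of all or part of chromosome 9 in resistant C4-2B cells may account for the -0.49 of the run, or for part of it, a hypothesis that only a DNA copy number measurement would decide.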
